A study of Homo sapiens with 35 samples.

How the data were processed

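The series holds 35 samples of the prostate cancer cell line DU145. The 6 RNA-seq libraries were analysed here: shLuciferase, shZMYND8 and shJARID1D, with 2 libraries each. The 29 chromatin immunoprecipitation and input samples were not analysed here. Per the labels' protocols, total RNA was extracted and libraries were made with a standard Illumina protocol. Selection of polyadenylated RNA and strandedness are not given in the sources used here, so overlapping and antisense genes are uncertain. The table's columns named Rac7_KO were taken as shZMYND8. This assumes that Rac7 stands for RACK7, which an antibody label of the series gives as another name of ZMYND8.

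The deposited file is a Cuffdiff gene count-tracking table of 28503 genes, and its deposited values are expected counts, that is fragment counts estimated per gene and library by the authors' software. The submitters' processing notes name TopHat2 2.0.12, Bowtie 1.1.2, Cuffdiff, edgeR 3.12.0 and the human build hg19 without saying which step each served, and the gene annotation is not given in the sources used here. The deposited counts carry a scaling: a single fragment has a value of 0.881 to 1.16, depending on the library, and after division by it 84.0% to 84.8% of the values under 1000 fragments lay within 0.05 of a whole number. The 18 variance columns, 3 per library, were not used, and the status marks served only to leave genes out. Estimated counts divide shared reads between near copies, so histone, IFITM, HLA and KDM5 genes are uncertain.

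The table marks 60 genes as not quantified (HIDATA) in at least 1 library and lists them at 0 there: 13 in all libraries and 36 only in shLuciferase replicate 2. These were left out, a choice the design had not foreseen. Genes marked as failed, 10 in all, were kept. Deposited counts were rounded to whole numbers and not otherwise rescaled. Gene names were matched to a RefSeq table of the human build GRCh38.p14 for names and neighbours only: 20932 names were current symbols and 1958 were synonyms.

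Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, factors by the trimmed mean of M values, filterByExpr on the group). The Benjamini-Hochberg method was applied over the 15867 genes left of 28443, with a threshold of 0.05. All 6 libraries shared the estimate of the spread, with 3 residual degrees of freedom, 6.8 prior degrees of freedom and a common biological coefficient of variation of 12.3%, without a block for the replicate number. The normalization factors ran from 0.966 to 1.057. Standard errors of log2 fold changes come from the fit, and SDs of CPM from the 2 libraries. Intervals on ratios of few fragments are 95% intervals and cover counting error only. A fold against libraries without fragments is a lower bound against a floor of 3 fragments per library.

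The choice of test, samples, gene lists, alternatives and named genes was made before the data were examined. Named genes in each knockdown were the targets and their near relatives, the 8 largest rises and 8 largest falls past the threshold, the metastasis genes recalled from the study, and up to 4 members of each list past the threshold by smallest adjusted p. The rises and falls needed a mean of at least 5 CPM over all libraries, a single gene name, and no overlap between the knockdown and control libraries. The direct comparison used the targets and the 5 largest differences each way, and the genes moved alike were the 6 each way with the largest smaller change. Of the list members so chosen, examples are printed. A single list member among those the rule names was left out of the text and is not reported here. The 31 gene lists held 846 members, 5 of them matched through a synonym and 1 not matched. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, Benjamini-Hochberg over the 30 lists with enough tested members). Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the edgeR p-values of that list only.

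Alternatives were other scalings (relative log expression, upper quartile, library totals only), no filter and a mean count of at least 50, DESeq2 1.42.0, limma voom, a fit of only the groups compared, a replicate block, leaving out each library, a threshold of 0.01 and a log2 fold change of at least 1. For lists they were camera with an estimated correlation, and fry. Added after the data were seen were 4 more: unquantified genes kept at 0, failed genes left out, the deposited scaling undone, and the most abundant small noncoding RNA entries left out. Simulated unchanged groups sharing simulated controls (50 simulations) showed what shared controls give when no gene is changed, at the spread pooled over all groups. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

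The scripts were tested on simulated data with 200 changed genes among 15647. In the simulated shZMYND8 comparison edgeR recovered 76% of the 2-fold and 89% of the 4-fold changes, with 6.2% false among 176 calls. In the simulated shJARID1D comparison it recovered 74% and 94%, with 8.7% false among 184 calls. Both shares of false calls lie above the threshold of 0.05. Camera ranked the changed list at place 1 and called 0 of 30 unchanged lists, and the simulated genes were independent, so this does not test the preset correlation.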

Results

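Gene expression was measured by RNA sequencing in DU145, an established prostate cancer cell line derived from a brain metastasis. The cells carried a short hairpin RNA against luciferase (shLuciferase, the control), against ZMYND8 (shZMYND8) or against JARID1D (shJARID1D). ZMYND8 is a chromatin protein that reads modified histone tails, and JARID1D, the product of the Y-linked gene KDM5D, removes methyl groups from lysine 4 of histone H3. Each group had 2 libraries, 6 in all. The deposited estimated fragment counts summed to 22925611 to 25001300 per library, from 20.7 M to 27.4 M fragments before the deposited scaling. A gene with no fragments in a library could lie at up to 0.109 to 0.145 CPM (counts scaled to a common library total), counting error only, and the 3 most abundant genes held 4.39% to 5.9% of a library's counts. Of 28443 genes, 15867 had enough counts to be tested.

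The libraries of a group differed by more than sampling noise. The chi-square statistic per gene was 41.4 between the shLuciferase libraries, 16.6 between the shZMYND8 libraries and 14.2 between the shJARID1D libraries. Across genes, which are not independent replicates, log2 CPM correlated at 0.984, 0.991 and 0.989 within these groups. The labels do not say that the libraries of a group came from separate cultures. Every p-value of edgeR or fry here therefore measures only the spread between these libraries, which may be technical. A camera p-value with the preset correlation sets a list's genes against the other genes tested, with genes rather than libraries as its units. It rests on the same libraries. With an estimated correlation camera is limited to the 3 residual degrees of freedom of the fit, so a list can lose its call also where its correlation is low. The labels name no sequencing batch. Unless another test is named, an adjusted p is edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and ± after a log2 fold change is its standard error with 2 libraries per group.

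The targeted genes were examined in every library as a check of the labels. ZMYND8 stood at 58.7 ± 8.48 CPM (SD, n = 2) in shLuciferase, 34.4 ± 1.59 CPM in shZMYND8 and 66.7 ± 4.22 CPM in shJARID1D. It was 1.71-fold lower in shZMYND8 than in shLuciferase (log2 fold change -0.77 ± 0.13, edgeR adjusted p = 0.00491). Without shZMYND8 replicate 2 the log2 fold change of ZMYND8 was -0.73 with an adjusted p of 0.0581, within a range of 0.00105 to 0.0581 over the libraries left out. KDM5D, the gene of JARID1D, stood at 59.6 ± 2.1 CPM in shLuciferase, 57.7 ± 3.1 CPM in shZMYND8 and 18.8 ± 1.18 CPM in shJARID1D. It was 3.18-fold lower in shJARID1D than in shLuciferase (-1.67 ± 0.12, edgeR adjusted p = 0.000831), and stayed past the threshold under every alternative tried. Neither knockdown moved the other target past the threshold: KDM5D differed by -0.05 in shZMYND8 (adjusted p = 0.83) and ZMYND8 by 0.18 in shJARID1D (adjusted p = 0.44). The related demethylase genes KDM5A, KDM5B and KDM5C, whose reads could be shared in part with KDM5D, did not pass either: their log2 fold changes were 0.15, 0.15 and 0.18 in shZMYND8 and 0.37, -0.05 and 0.01 in shJARID1D. Without shLuciferase replicate 1, KDM5A passed in shJARID1D (0.49, adjusted p = 0.0233, range over the libraries left out 0.0233 to 0.389).

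**Figure D1:**
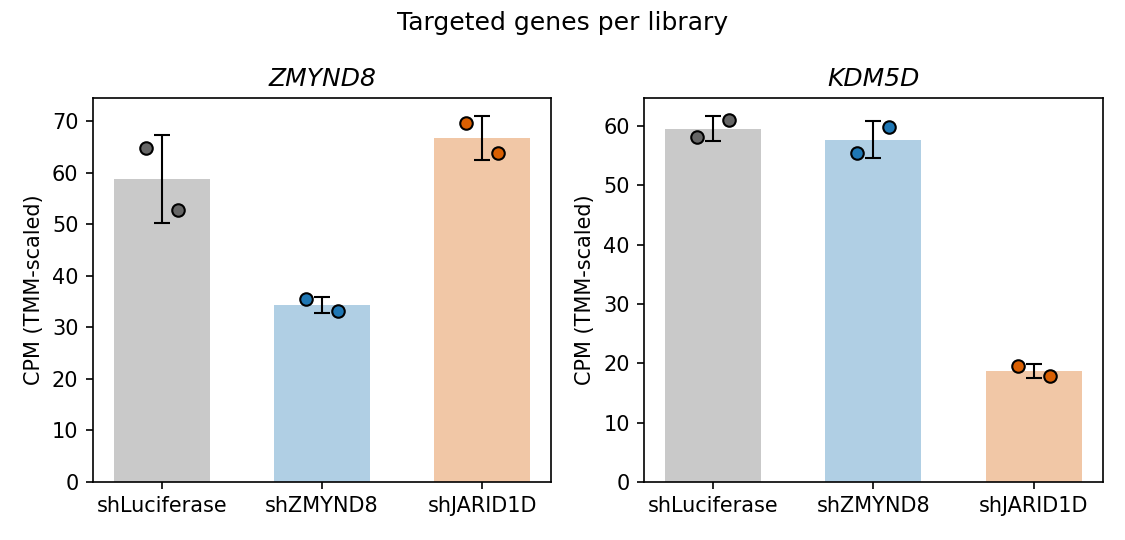
Expression of ZMYND8 and KDM5D in CPM scaled by the trimmed mean of M values, with bars for the mean of 2 libraries, error bars for the SD and a point per library. ZMYND8 stands at 35.5 and 33.2 CPM in the shZMYND8 libraries against 64.7 and 52.7 in shLuciferase, and KDM5D at 19.6 and 17.9 CPM in the shJARID1D libraries against 58.1 and 61.0.

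The comparison of shZMYND8 with shLuciferase asked which genes change when the RNA of the histone reader is lowered. Among genes with a mean of at least 5 CPM, the largest rises were in genes of the interferon response. IFI44L was 42.9-fold higher (5.42 ± 0.78), XAF1 41.4-fold (5.37 ± 0.73), OAS1 29.4-fold (4.88 ± 0.61), IFI27 22.5-fold (4.49 ± 0.72) and OAS2 19.0-fold (4.25 ± 0.54), with edgeR adjusted p from 0.00111 to 0.00344. IFITM1, whose reads may be shared with close relatives, was 30.2-fold higher (4.91 ± 0.93, adjusted p = 0.00731). UBD, a ubiquitin-like protein induced by cytokines, was 20.6-fold higher (4.36 ± 0.36, edgeR adjusted p = 0.000388), and the chemokine CCL5 was higher by 4.00 ± 0.37 on the log2 scale (edgeR adjusted p = 0.000455). In fragments, IFI44L had 16 and 1 in the control libraries against 656 and 198, XAF1 28 and 1 against 973 and 395, and IFITM1 20 and 3 against 665 and 129, so these folds rest on few control fragments. Without shLuciferase replicate 1 or replicate 2 the log2 fold change was 8.44 or 4.51 for IFI44L, 9.11 or 4.42 for XAF1 and 6.86 or 4.11 for IFITM1, and without shZMYND8 replicate 1 it was 4.27, 4.53 and 3.24. The other interferon genes named here varied too, OAS1 from 3.85 to 6.12, IFI27 from 2.89 to 5.23 and OAS2 from 3.29 to 5.22 over the libraries left out, all past the threshold. Large falls were in FBP1, an enzyme of gluconeogenesis (7.16-fold lower, -2.84 ± 0.21, edgeR adjusted p = 0.000315), and the cyclin gene CCNA1 (6.45-fold lower, -2.69 ± 0.23, edgeR adjusted p = 0.000425). TNFRSF11A, the receptor RANK, was 4.37-fold lower (-2.13 ± 0.18), the synaptic vesicle gene SV2A 3.92-fold lower (-1.97 ± 0.21) and the tight junction gene CLDN4 3.62-fold lower (-1.86 ± 0.20), with edgeR adjusted p of 0.000388, 0.000601 and 0.000727. The histone gene HIST1H3G, which has near copies, fell by 2.22 on the log2 scale (adjusted p = 0.00045). The largest fall among genes with a mean of at least 5 CPM was in the transcript entry BC010924 (-4.62 ± 0.90, adjusted p = 0.00828), but without shZMYND8 replicate 1, which had 0 of its fragments, the difference was -3.63 with an adjusted p of 0.0559, within 0.000711 to 0.0559 over the libraries left out.

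In all, 2574 genes changed between shZMYND8 and shLuciferase, 1410 higher and 1164 lower, and 595 of the higher and 208 of the lower genes differed at least 2-fold. Of the genes tested, 57.8% had no overlap between the libraries of both groups, where chance gives 33.3%. The count was 642 without shZMYND8 replicate 1 and 1005 without shZMYND8 replicate 2. When a group is left with a single library, that library is assumed to vary like the other groups.

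Genes of the interferon response rose as a group in shZMYND8. All 41 interferon-stimulated genes of the list fixed before the data were examined rose, with a median log2 fold change of 2.30. Adjusted over the list alone, all 41 then pass by construction. Examples are the transcription factor gene IRF7 (2.56 ± 0.27), the antiviral synthetase genes OASL (2.43 ± 0.27) and OAS3 (2.43 ± 0.28), and the antiviral GTPase gene MX1 (3.22 ± 0.37), with edgeR adjusted p from 0.000601 to 0.000817. The list stood apart from other genes by camera with a preset correlation (adjusted p = 3.25e-30), which was lost with an estimated correlation between members (adjusted p = 0.251 with an estimated correlation). Of 29 genes of NF-kB signalling and cytokines, 17 rose, 12 did not pass, and 21 rose and 1 fell when adjusted over the list alone. The list median was 0.91 (camera adjusted p = 1.6e-10, adjusted p = 0.225 with an estimated correlation). Examples are TRAF1 (1.70 ± 0.18), IRF1 (1.25 ± 0.14) and the cytokine gene IL6 (2.09 ± 0.24), with edgeR adjusted p from 0.000601 to 0.000806. Without shZMYND8 replicate 1, 33 interferon-stimulated genes and 11 NF-kB genes rose.

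Genes of mitosis fell as a group in shZMYND8. All 35 genes of the G2/M list fell, with a median of -0.78 (camera adjusted p = 9.85e-24, adjusted p = 0.251 with an estimated correlation). Adjusted over the list alone, all 35 then pass by construction. Examples are the kinetochore gene NUF2 (-1.46 ± 0.13), PRC1 of the central spindle (-1.22 ± 0.12), the centromeric histone gene CENPA (-1.07 ± 0.12) and the mitotic kinase gene CDK1 (-0.95 ± 0.12), with edgeR adjusted p from 0.000425 to 0.00105. The count of falling members was 11 without shZMYND8 replicate 1, where 33 had an unadjusted p under 0.05, and 28 without shZMYND8 replicate 2. Of 23 replication-dependent histone genes, which share reads with near copies, 12 fell and 11 did not pass, and 19 fell when adjusted over the list alone. The median was -0.61 (camera adjusted p = 1.07e-08, adjusted p = 0.359 with an estimated correlation), with HIST1H1B at -1.09 ± 0.17 (edgeR adjusted p = 0.00304). The histone count was 19 without shLuciferase replicate 1, 1 without shZMYND8 replicate 1 and 5 without shZMYND8 replicate 2. Of 34 S phase and E2F genes, 5 fell, 1 rose and 28 did not pass, and 7 fell and 1 rose when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.00322, adjusted p = 0.581 with an estimated correlation), and the camera call was lost without shLuciferase replicate 2 (adjusted p = 0.147, range over the libraries left out 4.48e-05 to 0.147). Falling S phase genes numbered 9 without shLuciferase replicate 1, 2 without either shJARID1D library and 0 by edgeR without either shZMYND8 library, where 6 and 10 of the list had an unadjusted p under 0.05.

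Among the epithelial genes that changed in shZMYND8 most fell, and among the extracellular matrix genes that changed most rose. Of 33 epithelial genes, 16 fell, 3 rose and 14 did not pass, with the same counts when adjusted over the list alone and a median of -0.66 (camera adjusted p = 2.19e-05, adjusted p = 0.225 with an estimated correlation). The adhesion gene EPCAM (-1.68 ± 0.17) and the desmosome gene DSP (-1.33 ± 0.14) fell, while the tight junction gene CLDN1 rose 4.71-fold (2.24 ± 0.15), with edgeR adjusted p of 0.000546, 0.000562 and 0.000262. Of 29 collagen and laminin genes, 16 rose, 2 fell and 11 did not pass, and 17 rose and 2 fell when adjusted over the list alone. Their median was 0.65 (camera adjusted p = 7.2e-07, adjusted p = 0.251 with an estimated correlation). The basement membrane genes COL4A1 (1.83 ± 0.17), LAMB1 (0.92 ± 0.11) and LAMA1 (0.78 ± 0.11) and the collagen gene COL16A1 (2.35 ± 0.29) rose, with edgeR adjusted p from 0.00045 to 0.0021. Of 24 mesenchymal genes, 10 rose, 14 did not pass, and 11 rose when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 6.2e-05, adjusted p = 0.225 with an estimated correlation). FSTL1 (0.84 ± 0.13) and COL5A2 (1.08 ± 0.17) are examples (edgeR adjusted p = 0.00251 and 0.00364). COL5A2 and other collagen genes of the mesenchymal list also belong to the collagen and laminin list. The mesenchymal list shares an integrin gene with the integrin list too, so these lists are not independent of each other. Of 17 integrin genes, 6 rose, 1 fell and 10 did not pass, and 8 rose and 1 fell when adjusted over the list alone. ITGA11 (2.78 ± 0.44) and ITGA2 (0.96 ± 0.14), both collagen receptors, rose, and ITGB4 of hemidesmosomes fell (-0.90 ± 0.12), with edgeR adjusted p from 0.0016 to 0.00323. The integrin median was 0.27 (camera adjusted p = 0.0428, adjusted p = 0.251 with an estimated correlation), and this call was lost without shLuciferase replicate 2 (0.0597) or shZMYND8 replicate 2 (0.09), within 0.0316 to 0.09. Without shZMYND8 replicate 1 or replicate 2 there were 8 or 9 falling epithelial genes, 8 or 7 rising collagen and laminin genes, 2 or 4 rising mesenchymal genes and 2 or 3 rising integrin genes.

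Lists of signalling targets also passed in shZMYND8. Of 28 immediate early genes, 10 rose, 18 did not pass, and 12 rose when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.000141, adjusted p = 0.251 with an estimated correlation). Examples are the transcription factor genes KLF4 (2.08 ± 0.20), KLF2 (2.19 ± 0.23), NR4A2 (2.15 ± 0.24) and ATF3 (1.29 ± 0.14), with edgeR adjusted p from 0.00051 to 0.00076. Of 23 TGF-beta targets, 10 rose, 1 fell and 12 did not pass, and 12 rose and 1 fell when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.00127, adjusted p = 0.225 with an estimated correlation). LTBP2 (1.09 ± 0.11), BAMBI (1.58 ± 0.17) and TGFBI (0.96 ± 0.12) rose, and PMEPA1 fell (-1.21 ± 0.12), with edgeR adjusted p from 0.000498 to 0.000979. LTBP2 and TGFBI encode matrix-associated proteins, while BAMBI and PMEPA1 encode inhibitors of the pathway. Of 25 YAP targets, 7 rose, 1 fell and 17 did not pass, and 9 rose and 1 fell when adjusted over the list alone. IGFBP3 (2.31 ± 0.18), ANKRD1 (1.55 ± 0.19) and the Hippo kinase gene LATS2 (1.07 ± 0.14) rose, and the tissue factor gene F3 fell (-1.21 ± 0.15), with edgeR adjusted p from 0.00035 to 0.00155. The YAP median was 0.33 (camera adjusted p = 0.0138, adjusted p = 0.584 with an estimated correlation), and this call was lost without shLuciferase replicate 1 (0.066) or shZMYND8 replicate 2 (0.0989), within 0.000628 to 0.0989. Of 28 genes of ER stress and ATF4, 4 rose, 24 did not pass, and 7 rose when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.000786, adjusted p = 0.251 with an estimated correlation). ATF3 is in this list too, and SESN2 rose by 0.82 ± 0.14 (edgeR adjusted p = 0.00493). Without shZMYND8 replicate 1 the rising members numbered 6 of the immediate early list and 5 of the TGF-beta list. Without shZMYND8 replicate 2 they numbered 6 of the TGF-beta list and 4 of the YAP list. Rising ER stress genes numbered 7 without shLuciferase replicate 2 and 2 without shJARID1D replicate 2.

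The remaining lists past the camera threshold in shZMYND8 had few changed members. Of 25 genes of cholesterol synthesis, 4 fell, 1 rose and 20 did not pass, with the same counts when adjusted over the list alone and a median of -0.26 (camera adjusted p = 0.00829, adjusted p = 0.255 with an estimated correlation). LSS, an enzyme of the pathway, fell (-0.75 ± 0.12, edgeR adjusted p = 0.00388) and lost the call without shZMYND8 replicate 1 (0.0583, range 0.000997 to 0.0583). Falling cholesterol genes numbered 7 without shLuciferase replicate 2, 2 without shZMYND8 replicate 2 and 0 by edgeR without shZMYND8 replicate 1, where 7 of the list had an unadjusted p under 0.05. Of 21 genes of the NuRD complex and of known ZMYND8 partners, 4 fell and 17 did not pass, with the same counts when adjusted over the list alone and a median of -0.24 (camera adjusted p = 0.0101, adjusted p = 0.251 with an estimated correlation). The largest fall among them was in MBD2 (-0.67 ± 0.12, edgeR adjusted p = 0.00659), which lost the call without shZMYND8 replicate 1 (0.0877, range 0.00212 to 0.0877). Falling NuRD genes numbered 7 without shLuciferase replicate 1, 1 without shZMYND8 replicate 2 or either shJARID1D library, and 0 by edgeR without shZMYND8 replicate 1, where 2 had an unadjusted p under 0.05. Of 6 stromal markers, COL1A1 rose (1.65 ± 0.42, edgeR adjusted p = 0.026), 5 did not pass, and 4 rose when adjusted over the list alone. The stromal median was 1.15 (camera adjusted p = 0.0464, adjusted p = 0.251 with an estimated correlation). COL1A1 and COL3A1 also belong to the collagen list, and COL1A1, COL3A1 and TAGLN to the mesenchymal list. The stromal call was lost without shLuciferase replicate 1 (0.0507), shLuciferase replicate 2 (0.0769) or shZMYND8 replicate 2 (0.053), with library totals only (0.0555) and without small noncoding RNA entries (0.0507), within 0.00917 to 0.251 over its alternatives. COL1A1 itself was lost without shLuciferase replicate 2 (adjusted p = 0.0756), shZMYND8 replicate 1 (0.136) or shZMYND8 replicate 2 (0.103), within 0.0118 to 0.136.

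The other lists did not pass camera in shZMYND8. Of 25 p53 targets, 9 rose and 1 fell (9 and 2 when adjusted over the list alone, camera adjusted p = 0.0508), and of 30 genes of matrix proteolysis 8 rose and 2 fell (11 and 3 when adjusted over the list alone, camera adjusted p = 0.0947). Of 24 angiogenesis factors 6 rose and 4 fell (8 and 4 when adjusted over the list alone, camera adjusted p = 0.0947), and of 34 hypoxia genes 7 rose and 3 fell (7 and 4 when adjusted over the list alone, camera adjusted p = 0.416). Enzymes of H3K4 methylation, with 4 of 25 higher and 3 lower (8 and 5 when adjusted over the list alone), gave a camera adjusted p of 0.608. Enzymes of H3K14 acetylation, with 1 of 18 higher and 1 lower (0 and 0 when adjusted over the list alone, while 3 of the list had an unadjusted p under 0.05 by edgeR), gave 0.929. Of 19 genes of fatty acid synthesis 3 fell (4 when adjusted over the list alone, camera adjusted p = 0.0985), and of 19 glycolysis genes 2 rose and 2 fell (2 and 5 when adjusted over the list alone, camera adjusted p = 0.104). Of 42 oxidative phosphorylation genes 2 fell (1 when adjusted over the list alone, camera adjusted p = 0.0947), and of 52 ribosomal protein genes 1 rose and 2 fell (1 and 0 when adjusted over the list alone, camera adjusted p = 0.398). The p53 list passed camera with library totals only (0.0448) and passed fry (0.00917), within 0.00917 to 0.251 over its alternatives. The lists of matrix proteolysis (0.0182, range over its alternatives 0.0182 to 0.255) and angiogenesis factors (0.0289, range 0.0289 to 0.255) also passed fry. The camera call for oxidative phosphorylation was gained without shLuciferase replicate 1 (0.00154) or shZMYND8 replicate 1 (0.00586), within 0.00154 to 0.975, and that for glycolysis without shLuciferase replicate 1 (0.0297), within 0.0297 to 0.697. Without shZMYND8 replicate 1 or replicate 2 the rising members numbered 2 or 5 p53 targets, 3 or 3 genes of matrix proteolysis, 1 or 1 angiogenesis factors and 2 or 3 hypoxia genes. Without the same libraries the changed members, higher or lower, numbered 1 or 0 enzymes of H3K4 methylation, 0 or 1 genes of fatty acid synthesis, 0 or 1 of glycolysis, 0 or 1 of oxidative phosphorylation, 0 or 0 enzymes of H3K14 acetylation and 0 or 0 ribosomal protein genes by edgeR. There 9 or 8, 4 or 4, 3 or 5, 8 or 3, 3 or 0 and 5 or 4 members of these lists had an unadjusted p under 0.05. Without shLuciferase replicate 1, 6 glycolysis genes and 6 oxidative phosphorylation genes fell. Among markers of other cell types, 2 of 9 prostate luminal genes rose (2 when adjusted over the list alone, camera adjusted p = 0.416), and 2 of 7 blood cell markers rose (3 when adjusted over the list alone, camera adjusted p = 0.38). Of 12 prostate basal genes, 4 rose and 1 fell (5 and 2 when adjusted over the list alone, camera adjusted p = 0.763), with a median of -0.03 against a mean of 0.32. Without shZMYND8 replicate 1 edgeR called 0 of these luminal, blood cell and basal genes as higher, where 2, 1 and 5 of the lists had an unadjusted p under 0.05. Without shZMYND8 replicate 2 it called 2 and 2 luminal and blood cell genes as higher and 0 basal genes, where 8 of the basal list had an unadjusted p under 0.05. The neuroendocrine list had 4 tested members, none of them past the edgeR threshold and 1 with an unadjusted p under 0.05, and was not tested as a list.

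The study's title concerns metastasis-linked genes, and 8 such genes were recalled from the study before the data were examined. This list may have been chosen on these samples, so its counts are not independent evidence of a direction. In shZMYND8, 3 of the 6 tested genes rose, 1 fell and 2 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.258, with a median of 0.26 and a mean of 0.01). The growth factor receptor gene EGFR was 1.54-fold higher (0.63 ± 0.12, edgeR adjusted p = 0.009), with 225 and 270 CPM in the shZMYND8 libraries against 161 and 160 in shLuciferase. The transcription factor gene SNAI2 was 1.98-fold higher (0.99 ± 0.27, edgeR adjusted p = 0.0329), and CD44, the hyaluronan receptor, was 1.30-fold higher (0.37 ± 0.11, edgeR adjusted p = 0.049). The collagenase gene MMP1 was 4.09-fold lower (-2.03 ± 0.33, edgeR adjusted p = 0.00374), and was past the threshold whichever library was left out. VEGFA (0.00 ± 0.14) and MMP14 (0.14 ± 0.14) did not pass. In shJARID1D none of the 6 passed by edgeR, 3 of them had an unadjusted p under 0.05, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.831). There EGFR stood at -0.46 ± 0.12 (adjusted p = 0.0601), CD44 at -0.42 ± 0.11 (adjusted p = 0.0579), SNAI2 at 0.73 ± 0.27 (adjusted p = 0.137), MMP1 at 0.31 ± 0.29 (adjusted p = 0.56), VEGFA at 0.09 ± 0.14 and MMP14 at 0.05 ± 0.14. In shZMYND8 the count of rising genes was 1 without shLuciferase replicate 2 or shZMYND8 replicate 1, 2 without either shJARID1D library, and 0 by edgeR without shZMYND8 replicate 2, where 4 of the 6 had an unadjusted p under 0.05. MMP2 (1 fragment in all 6 libraries) and MMP3 (1 to 9 fragments per library) had too few counts to test. EGFR lost its call in shZMYND8 without shZMYND8 replicate 2 (0.48, adjusted p = 0.101, range 0.0125 to 0.101). SNAI2 lost it without shLuciferase replicate 2 (0.0883), shZMYND8 replicate 1 (0.182) or shZMYND8 replicate 2 (0.117), within 0.0287 to 0.182. CD44 lost it without shLuciferase replicate 2 (0.0931), shZMYND8 replicate 1 (0.238), shZMYND8 replicate 2 (0.201), shJARID1D replicate 1 (0.0956) or shJARID1D replicate 2 (0.108), within 0.0392 to 0.238. CD44 passed in shJARID1D without shLuciferase replicate 2 (adjusted p = 0.0436, range 0.0436 to 0.322).

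The comparison of shJARID1D with shLuciferase asked which genes change when the RNA of the H3K4 demethylase is lowered. Among genes with a mean of at least 5 CPM, the largest rises again held interferon-stimulated genes: IFITM1 was 19.7-fold higher (4.30 ± 0.94), IFI44L 16.3-fold (4.03 ± 0.81), OAS1 8.88-fold (3.15 ± 0.60), OAS2 5.19-fold (2.37 ± 0.53), MX1 4.43-fold (2.15 ± 0.35) and MX2 4.09-fold (2.03 ± 0.51), with edgeR adjusted p from 0.0144 to 0.0488. The folds of IFITM1 (342 and 117 fragments) and IFI44L (188 and 94) rest on the same few control fragments. Without shLuciferase replicate 1 the log2 fold change was 6.25 for IFITM1 and 7.04 for IFI44L. Without replicate 2 it was 3.5 and 3.1, and both calls were lost (adjusted p = 0.0793 and 0.0545, ranges over the libraries left out 0.0165 to 0.165 and 0.0128 to 0.131). With 1 control library left out OAS1 ran from 2.49 to 4.40, OAS2 from 1.80 to 3.35, MX1 from 1.87 to 2.48 and MX2 from 1.48 to 2.93, and without replicate 2 OAS2 and MX2 lost the call (0.0772 and 0.109, ranges 0.0111 to 0.165 and 0.0129 to 0.226). The guanylate-binding protein gene GBP4 was 4.67-fold higher (2.22 ± 0.39, edgeR adjusted p = 0.0172). IGFBP3, a carrier of insulin-like growth factors, was 5.77-fold higher (2.53 ± 0.18, edgeR adjusted p = 0.000831). The largest fall at this level was in DKK3, a secreted relative of the Wnt inhibitors (3.51-fold lower, -1.81 ± 0.15, edgeR adjusted p = 0.00107). The epithelial splicing factor gene ESRP2 (-1.48 ± 0.18), LGI2 (-1.45 ± 0.21), the transcription factor gene TFCP2L1 (-1.27 ± 0.22), the glycosyltransferase gene GALNT10 (-1.26 ± 0.13), the receptor kinase gene AXL (-1.26 ± 0.20) and the myosin kinase gene MYLK (-1.22 ± 0.12) also fell. Their edgeR adjusted p ran from 0.00333 to 0.0168. In all, 912 genes changed, 469 higher and 443 lower, and 190 of the higher and 49 of the lower genes differed at least 2-fold. Of the genes tested, 51.9% had no overlap between the libraries of both groups, where chance gives 33.3%.

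Most calls in shJARID1D were lost when either of its libraries was left out. Such a fit has fewer libraries to estimate the spread, so a lost call need not mean that the libraries disagree. The count of changed genes was 16 without shJARID1D replicate 1 and 22 without shJARID1D replicate 2. It was 2145 without shLuciferase replicate 1, 407 without shZMYND8 replicate 1 and 394 without shZMYND8 replicate 2. Of the 39 named genes past the threshold here, IGFBP3, DKK3, KDM5D and GALNT10 stayed past it without shJARID1D replicate 1, and IGFBP3, DKK3, KDM5D, IRF7, AXL and MYLK without shJARID1D replicate 2. Of the 39, 24 lost the call with no filter on low counts, 8 without shLuciferase replicate 2, 7 and 8 without shZMYND8 replicate 1 and replicate 2, 6 by limma voom and 5 with only the 2 groups compared. The lone shJARID1D library is then assumed to vary like the other groups.

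Among the lists in shJARID1D, interferon-stimulated genes again led. Of 41, 26 rose, 15 did not pass, and 40 rose when adjusted over the list alone, with a median of 1.44 (camera adjusted p = 2.41e-26, adjusted p = 0.816 with an estimated correlation). IRF7 (1.95 ± 0.27), IRF9 (1.52 ± 0.21) and OAS3 (1.57 ± 0.27) are examples, with edgeR adjusted p of 0.00805, 0.00833 and 0.0161. The count was 12 without shLuciferase replicate 2, 1 without shJARID1D replicate 2 and 0 by edgeR without shJARID1D replicate 1, where 39 had an unadjusted p under 0.05. Of 29 NF-kB and cytokine genes, 3 rose, 1 fell and 25 did not pass, and 17 rose and 3 fell when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 8.11e-05, adjusted p = 0.816 with an estimated correlation). PTGS2, a prostaglandin synthase gene (2.69 ± 0.52), RELB (0.86 ± 0.18) and IRF1 (0.65 ± 0.14) rose, and BIRC3, an inhibitor of apoptosis, fell (-0.70 ± 0.14), with edgeR adjusted p from 0.0221 to 0.0297. Of 28 immediate early genes, 7 rose, 21 did not pass, and 9 rose and 1 fell when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00227, adjusted p = 0.816 with an estimated correlation). ATF3 (0.88 ± 0.15), KLF4 (1.02 ± 0.20), FOS (0.91 ± 0.18) and BTG2 (1.06 ± 0.21) are examples, with edgeR adjusted p from 0.0148 to 0.0251. This list's camera call was lost without shLuciferase replicate 1 (0.0569, range over the libraries left out 0.000501 to 0.0569). Rising NF-kB genes numbered 9 without shLuciferase replicate 1, 5 without shLuciferase replicate 2 and 1 without either shZMYND8 library. Rising immediate early genes numbered 4 without either shZMYND8 library. Without shJARID1D replicate 1 or replicate 2, edgeR called 0 genes of either list, while 18 or 16 NF-kB genes and 9 or 13 immediate early genes had an unadjusted p under 0.05.

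A pair of other lists passed as lower in shJARID1D. Of 35 G2/M genes, AURKA, a mitotic kinase gene, fell (-0.70 ± 0.14, edgeR adjusted p = 0.0234) and 34 did not pass, and 8 fell when adjusted over the list alone. The median was -0.26 (camera adjusted p = 3.91e-07, adjusted p = 0.909 with an estimated correlation). Falling G2/M genes numbered 3 without either shLuciferase library and 0 by edgeR without shJARID1D replicate 1 or replicate 2, where 3 and 15 had an unadjusted p under 0.05. Of 12 prostate basal genes, 4 fell, 1 rose and 7 did not pass, and 7 fell and 2 rose when adjusted over the list alone. The median was -0.45 and the mean -0.10 (camera adjusted p = 0.00522, adjusted p = 0.816 with an estimated correlation). DKK3, the caveolin genes CAV1 (-0.70 ± 0.13) and CAV2 (-0.69 ± 0.11), and the integrin gene ITGA6 (-0.63 ± 0.15) fell, with edgeR adjusted p from 0.00107 to 0.0455. Without either shJARID1D library 1 prostate basal gene fell. None of the 29 collagen and laminin genes and none of the 23 histone genes passed edgeR in shJARID1D, with 7 and 3 of them at an unadjusted p under 0.05 (camera adjusted p = 0.494 and 0.831). The histone list passed camera without shLuciferase replicate 2 (0.0371) or shJARID1D replicate 1 (0.00234), within 0.00234 to 0.783. Of the 33 epithelial genes 2 rose and 6 fell (5 and 7 when adjusted over the list alone, camera adjusted p = 0.343). Without either shZMYND8 library 1 epithelial gene fell, and without shJARID1D replicate 1 or replicate 2 edgeR called 0 as lower, where 13 and 12 of the list had an unadjusted p under 0.05. Of the 24 mesenchymal genes 2 fell (2 when adjusted over the list alone, camera adjusted p = 0.817).

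The question of which genes both knockdowns moved alike was asked against the same 2 control libraries. In both, 370 genes changed the same way, 259 higher and 111 lower, and 34 changed in opposite directions. The genes with the largest smaller rise were IFITM1, IFI44L, GBP5, OAS1, CEACAM1 and OAS2. CEACAM1, a cell adhesion molecule, rose by 3.57 ± 0.52 in shZMYND8 and 2.53 ± 0.55 in shJARID1D (edgeR adjusted p = 0.00226 and 0.0331). GBP5, a guanylate-binding protein gene, had 1 fragment in each control library, and its ratio to the control was 34.9 in shZMYND8 (95% counting interval 9.35 to 293) and 12.6 in shJARID1D (3.13 to 110). Among the genes lower in both, BDH1, a ketone body enzyme gene, differed by -1.24 ± 0.33 and -1.45 ± 0.33, the bicarbonate transporter gene SLC4A4 by -1.16 ± 0.14 and -1.08 ± 0.14, and C12orf75 by -1.46 ± 0.13 and -1.08 ± 0.12, in shZMYND8 and shJARID1D (edgeR adjusted p from 0.000425 to 0.0369). The transcript entry BX648939 differed by -1.07 ± 0.27 in both (edgeR adjusted p = 0.0256 and 0.0488). In shZMYND8, BDH1 lost the call without shLuciferase replicate 2 (0.12), shZMYND8 replicate 1 (0.14) or shZMYND8 replicate 2 (0.166), within 0.00601 to 0.166, and BX648939 without shLuciferase replicate 1 (0.0887), shZMYND8 replicate 1 (0.151) or shZMYND8 replicate 2 (0.136), within 0.0167 to 0.151. AX747150 was lower by a ratio of 42.1 in shZMYND8 (95% counting interval 16.1 to 157) and by -2.38 ± 0.42 on the log2 scale in shJARID1D (edgeR adjusted p = 0.017). AK057897 had no fragments in either shZMYND8 library, which makes it at least 14.5-fold lower there against a floor of 3 fragments per library, and it differed by -2.37 ± 0.46 in shJARID1D (edgeR adjusted p = 0.0251).

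Comparisons against the same controls share their chance values. In 50 simulations all libraries, the controls included, were drawn anew from the control means, with the spread pooled over the groups. A mean of 0.24 genes was higher in both (at most 2) and 0.16 lower in both (at most 2). By edgeR 0 were called in opposite directions in any simulation, against 34 in the data. No gene was changed in either simulated knockdown, so few genes could be called and joint counts near 0 follow from the setting. These counts do not show how often shared controls carry a gene changed by a single knockdown past the threshold in both. The simulated controls also varied less than the real pair, as the covariances below show, so these counts may understate what chance gives. The share of genes with the same sign in both was 64%, below the mean of 66.6% in the simulations (at most 67.2%). Independent lists of these sizes would share 41.7 higher and 32.5 lower genes, and 73.8 in opposite directions. The correlation of the log2 fold changes across genes was 0.49, against 0.50 in the simulations. For equal unchanged groups that share controls, this correlation and the share of same signs are set by the design, whatever the spread. Values near the simulated ones therefore show neither shared effects nor their absence. The covariance was 0.133 against 0.0358, a difference of 0.097. A covariance of 0.0631 is given by the spread of the control libraries themselves, which leaves 0.0697. Without the interferon-stimulated genes the correlation was 0.46 and the covariance 0.12. The control libraries were too few to split, so part of the excess may come from the shared controls. The count of 370 was 970 without shLuciferase replicate 1, 127 without shZMYND8 replicate 1 and 168 without shZMYND8 replicate 2, and 10 and 11 without shJARID1D replicate 1 and replicate 2.

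**Figure D2:**
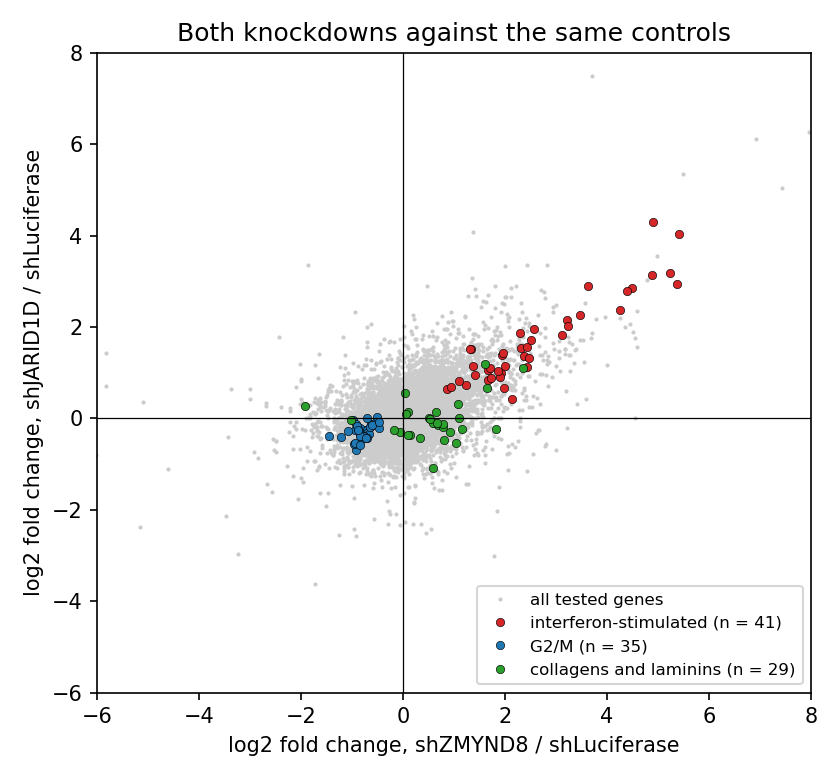
Log2 fold change of each tested gene in shZMYND8 (horizontal axis) and shJARID1D (vertical axis), both over the same shLuciferase libraries, with 41 interferon-stimulated, 35 G2/M and 29 collagen and laminin genes coloured and 12 genes outside the axes not drawn. The interferon-stimulated genes lie above 0 on both axes, and the G2/M genes lie at a median of -0.78 on the horizontal and -0.26 on the vertical axis.

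The comparison of shZMYND8 with shJARID1D tested the difference between the knockdown effects itself. The control libraries cancel from its log2 fold changes but still enter the shared estimate of the spread, and so its p-values by edgeR. GLIPR1 was 10.1-fold higher in shZMYND8 than in shJARID1D (3.33 ± 0.25, edgeR adjusted p = 0.000269), CCL5 7.05-fold (2.82 ± 0.34, edgeR adjusted p = 0.00133), UBD 5.16-fold (2.37 ± 0.30, edgeR adjusted p = 0.00173) and the keratin gene KRT81 4.88-fold (2.29 ± 0.26, edgeR adjusted p = 0.00101). CCNA1 was 8.13-fold lower (-3.02 ± 0.23), MMP1 5.08-fold lower (-2.35 ± 0.33), SV2A 4.90-fold lower (-2.29 ± 0.21) and HIST1H3G 5.24-fold lower (-2.39 ± 0.21), with edgeR adjusted p from 0.000269 to 0.00246. XAF1 (2.42 ± 0.56, edgeR adjusted p = 0.0208) lost its call without shZMYND8 replicate 1 (0.202), shJARID1D replicate 1 (0.0512) or shJARID1D replicate 2 (0.131), within 0.00244 to 0.202. BC010924 (-3.51 ± 0.92, edgeR adjusted p = 0.0313) lost it without the same libraries (0.142, 0.113 and 0.0632), within 0.00274 to 0.142. In all, 1376 genes were higher and 1114 lower in shZMYND8, 2490 together, and 374 and 261 of them differed at least 2-fold. Of the genes tested, 65.4% had no overlap between the libraries of both groups, where chance gives 33.3%. The count was 602 without shZMYND8 replicate 1, 551 without replicate 2, 627 without shJARID1D replicate 1 and 632 without replicate 2. It was 4191 and 4179 without shLuciferase replicate 1 and replicate 2, and 4252 when only the 4 libraries compared were fitted.

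Lists were also compared between the knockdowns. Of 35 G2/M genes 17 were lower in shZMYND8 than in shJARID1D (28 when adjusted over the list alone), with a median difference of -0.46 (camera adjusted p = 1.43e-13, adjusted p = 0.438 with an estimated correlation). Of 23 histone genes 12 were lower (20 when adjusted over the list alone), with a median of -0.60 (camera adjusted p = 4.05e-09, adjusted p = 0.438 with an estimated correlation). Of 29 collagen and laminin genes 17 were higher and 1 lower (21 and 3 when adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.05e-07, adjusted p = 0.341 with an estimated correlation). Of 41 interferon-stimulated genes 11 were higher (26 when adjusted over the list alone), with a median of 0.85 (camera adjusted p = 3.64e-07, adjusted p = 0.603 with an estimated correlation). Of 25 YAP targets 13 were higher and 2 lower (15 and 2 when adjusted over the list alone), with a median of 0.55 (camera adjusted p = 3.21e-05, adjusted p = 0.451 with an estimated correlation). Epithelial genes were lower in 15 and higher in 6 of 33 cases (15 and 7 when adjusted over the list alone), with a median of -0.60 (camera adjusted p = 0.00325, adjusted p = 0.341 with an estimated correlation). Mesenchymal genes were higher in 9 of 24 cases (12, and 1 lower, when adjusted over the list alone), with a median of 0.55 (camera adjusted p = 2.35e-05, adjusted p = 0.306 with an estimated correlation). In all, 14 of the 30 lists passed camera in this comparison, against 16 in shZMYND8 and 5 in shJARID1D. None of the 30 passed with an estimated correlation in any of the 3 comparisons. With that setting camera gave an unadjusted p under 0.05 for 4, 0 and 3 lists in shZMYND8, in shJARID1D and between them. The estimated correlation was 0.88 for interferon-stimulated and 0.68 for G2/M genes, but -0.02 for mesenchymal, -0.01 for integrin and -0.02 for TGF-beta genes. These last 3 lie below the preset 0.01, so a high correlation is not what lost their calls. Camera with an estimated correlation is also limited to the 3 residual degrees of freedom, rather than the number of genes. The mesenchymal list in shZMYND8 went from an unadjusted camera p of 1.45e-05 to 0.0171. For lists with a high correlation, the share of the loss due to the correlation was not tested. By fry, which asks whether a list's genes move one way on balance, 16, 0 and 11 lists passed. Without shZMYND8 replicate 1 or replicate 2 the counts above were 3 or 6 lower G2/M genes, 2 or 2 histone genes, 7 or 7 higher collagen and laminin genes, 2 or 24 interferon-stimulated genes, 7 or 3 YAP targets, 9 or 6 lower epithelial genes and 4 or 5 mesenchymal genes. Without shJARID1D replicate 1 or replicate 2 they were 9 or 5, 11 or 2, 8 or 8, 2 or 1, 3 or 7, 8 or 9 and 4 or 5 in the same order. Without either shLuciferase library the interferon-stimulated count was 22 and the histone count 20.

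**Figure D3:**
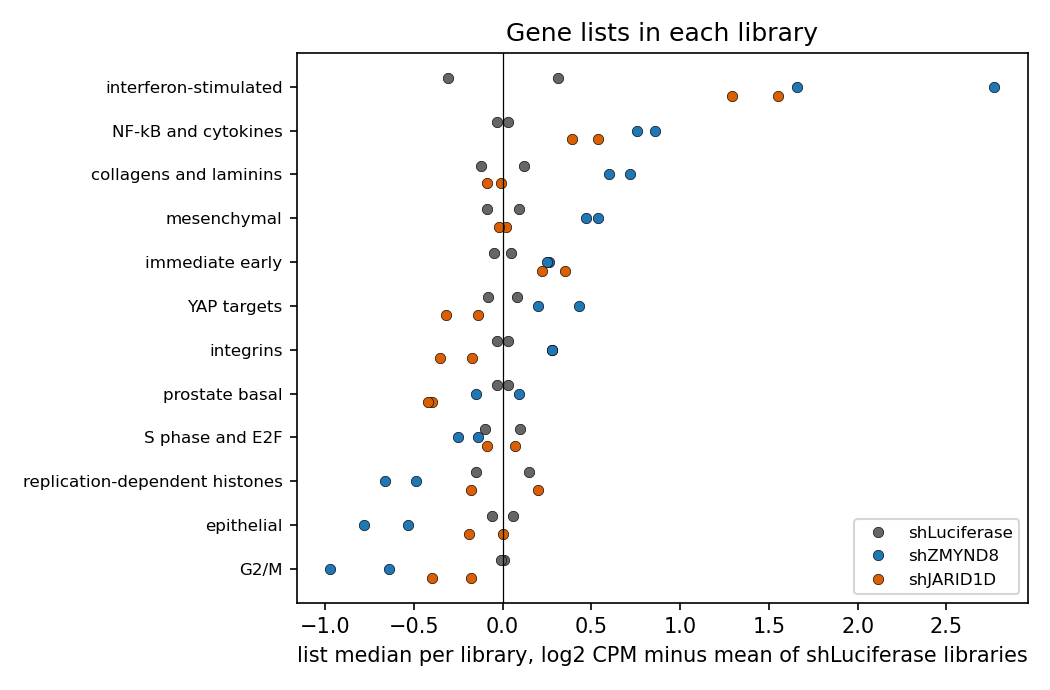
Median over the members of 12 gene lists in each of the 6 libraries, as log2 CPM minus the mean of the shLuciferase libraries, with a point per library coloured by group. Interferon-stimulated genes lie at 2.77 and 1.66 in the shZMYND8 libraries and 1.55 and 1.29 in the shJARID1D libraries against 0.31 and -0.31 in shLuciferase, and G2/M genes at -0.97 and -0.64 in shZMYND8 and -0.40 and -0.18 in shJARID1D.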

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

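The tests of the difference between the knockdowns were planned, and the other settings beside them are the alternatives of the next part; no explanation was tested for these results. Each is a difference between groups: the effects of shZMYND8 and shJARID1D, against the same controls, had estimates of opposite sign and differed by a test of the difference itself. The test bears on the difference, not on the sign in either knockdown.

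BIRC3, an inhibitor of apoptosis, differed by 1.87 ± 0.14 on the log2 scale (edgeR adjusted p = 0.000269), with 1.17 in shZMYND8 and -0.70 in shJARID1D. EGFR differed by 1.09 ± 0.13 (edgeR adjusted p = 0.00101), with 0.63 and -0.46. CD44 differed by 0.80 ± 0.11 (edgeR adjusted p = 0.00255), with 0.37 and -0.42. MMP1 differed by -2.35 ± 0.33 (edgeR adjusted p = 0.00246), with -2.03 and 0.31; the value in shJARID1D did not pass (adjusted p = 0.56) and was -0.05 without shLuciferase replicate 1. These 4 differences stayed past the threshold under every alternative, with a largest adjusted p of 0.00513 for BIRC3, 0.0173 for EGFR, 0.0454 for CD44 and 0.0286 for MMP1. The fall in shJARID1D passed for BIRC3 alone (adjusted p = 0.0227), and it was lost without shZMYND8 replicate 2 (0.0516), shJARID1D replicate 1 (0.165) or shJARID1D replicate 2 (0.14), within 0.00493 to 0.165.

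The integrin list had a median difference of 0.58 (camera adjusted p = 0.000991, 0.306 with an estimated correlation), with medians of 0.27 in shZMYND8 and -0.29 in shJARID1D, where the mean was -0.01. Over the libraries left out these medians ran from 0.25 to 0.48 and from -0.38 to -0.15. The YAP target list had a median difference of 0.55 (camera adjusted p = 3.21e-05, 0.451 with an estimated correlation), with medians of 0.33 and -0.30, which ran from 0.17 to 0.42 and from -0.33 to -0.16 over the libraries left out. Leaving out any library kept both past the threshold (up to 0.00307 and 0.00166), but by fry the YAP target call was lost (0.0814). In shJARID1D itself neither list passed camera (0.188 and 0.17), except YAP targets without shJARID1D replicate 2 (0.00589, range 0.00589 to 0.674).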

How the results depend on the processing

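The alternatives were planned before the data were examined, except 4 added after the results were seen. Of the named genes' values under the alternatives, 2830 kept their direction and side of the threshold, 238 lost the call, 27 gained it and 9 changed sign, with a value of 0.00 never counted as a change of sign. For single lists 1180 values kept their side of the threshold, 60 lost the call and 20 gained it. Their direction was compared only for lists past the threshold, where none turned. Depth limits what can be seen: a gene without fragments can be placed only below 0.109 to 0.145 CPM. A group left with a single library is assumed to vary like the other groups.

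The count in shZMYND8 (2574) was 1002 at a threshold of 0.01, 803 with a log2 fold change of at least 1, and 642 to 3222 over the libraries left out. The count in shJARID1D (912) was 204 without a filter, 449 with only the groups compared, 77 at 0.01, 239 with the fold limit and 16 to 2145 over the libraries left out. The count between the knockdowns (2490) was 1560, 4252, 761, 635 and 551 to 4191 in the same order, and that of genes moved alike (370) was 93, 203, 30, 113 and 10 to 970. Stricter limits lower a count by construction; for the other settings, which raised some counts and lowered others, the cause was not tested. DESeq2 called 2641, 1359, 2606 and 533 genes and limma voom 2517, 819, 2467 and 327, in the same order of comparisons.

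The labels do not say what the replicate numbers stand for. The differences between replicates correlated at 0.09, 0.17 and 0.1 between groups. The interferon-stimulated median was higher in replicate 1 in shLuciferase (0.31 against -0.31), shZMYND8 (2.77 against 1.66) and shJARID1D (1.55 against 1.29). The G2/M median was higher there in shLuciferase (0.01 against -0.01), but lower in shZMYND8 (-0.97 against -0.64) and shJARID1D (-0.40 against -0.18). A batch shared by replicate number cannot be excluded. With a replicate block the counts were 3699, 2073, 3785 and 864, and the block changed no list's call.

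The split of higher and lower genes moved both ways. In shJARID1D (469 and 443) it was 540 and 335 by upper quartile and 709 and 294 by library totals, but 454 and 473 by RLE size factors, 585 and 774 by DESeq2 and 965 and 1180 without shLuciferase replicate 1. In shZMYND8 (1410 and 1164) it was 1515 and 970 by library totals and 1316 and 1325 by DESeq2. Between the knockdowns (1376 and 1114) it was 1140 and 1392 by library totals. For genes moved alike (259 and 111) it was 294 and 73 by upper quartile and 372 and 64 by library totals. By RLE size factors that split was 253 and 122, and by DESeq2 322 and 211. The median of all genes shifted by at most 0.089.

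ZMYND8 in shZMYND8 ran from -0.92 to -0.62 over the libraries left out. Genes that changed sign had not passed the threshold. In shZMYND8 these were KDM5D (-0.11 to 0.01) and MMP14 (-0.05 to 0.35) over the libraries left out, and VEGFA, not counted because it stood at 0.00, ran from -0.10 to 0.09. In shJARID1D they were KDM5B (-0.18 to 0.08, and 0.03 by library totals), KDM5C (-0.09 to 0.11), VEGFA (-0.06 to 0.22), MMP1 (-0.05 to 0.80) and MMP14 (-0.14 to 0.26). The cause was not tested.

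Lists past the threshold (16 in shZMYND8, 5 in shJARID1D, 14 between them) numbered 0, 0 and 0 by camera with an estimated correlation, with a smallest adjusted p of 0.225, 0.816 and 0.306. By fry they numbered 16, 0 and 11, where 17, 7 and 16 had an unadjusted p under 0.05. Of the lists past fry, 13, 0 and 9 had also passed camera. Fry lost S phase (0.281), YAP targets (0.156) and histones (0.104) in shZMYND8, and interferon-stimulated genes (0.405), G2/M (0.0546), S phase (0.266), YAP targets (0.0814) and histones (0.0973) between the knockdowns. Over the libraries left out they numbered 13 to 17, 5 to 7 and 14 to 16.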

Other observations

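The gene lists, genes and tests of this part were chosen after the results were seen. Of 17 genes of MHC class I presentation, whose HLA members share reads, 16 rose in shZMYND8 (17 when adjusted over the list alone), with a median of 0.97 (camera unadjusted p = 1.61e-14, 0.0871 with an estimated correlation). In shJARID1D 3 rose (15 when adjusted over the list alone), with a median of 0.50 (camera unadjusted p = 7.94e-10, 0.138 with an estimated correlation). The proteasome gene PSMB9 rose in both (1.45 ± 0.17 and 1.04 ± 0.17, edgeR adjusted p = 0.000986 and 0.015), and the peptide transporter gene TAP1 passed in shZMYND8 (1.32 ± 0.18, edgeR adjusted p = 0.0016). Of 12 complement genes, 5 rose in shZMYND8 and 3 in shJARID1D (5 and 6 higher, 1 and 0 lower, when adjusted over the list alone). C3 rose by 3.01 ± 0.30 and 1.15 ± 0.28 (edgeR adjusted p = 0.000546 and 0.046). Of 7 genes of CDK inhibitors, 2 rose and 3 fell in shZMYND8, and edgeR called 0 in shJARID1D (1 higher when adjusted over the list alone).

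The interferon gene IFNB1 had no fragments in either shLuciferase library, 22 and 11 in shZMYND8 and 5 and 10 in shJARID1D. It was at least 4.90-fold higher in shZMYND8 (edgeR adjusted p = 0.0107) and at least 2.78-fold in shJARID1D (edgeR adjusted p = 0.0518). IFNL1 had 4 and 0 fragments in shLuciferase, 32 and 17 in shZMYND8 and 2 and 3 in shJARID1D.

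Interferon-stimulated genes were higher in both knockdowns. Low values in shLuciferase replicate 2 could raise both, but without that library the smaller list median was still 1.26. The smallest median over the other scalings was 1.43. These scalings shifted the median of all genes by at most 0.089. The choice among them changes too little for this test to decide on scaling. A scaling factor moves all genes of a library alike, however. The median of all genes was -0.005 in shZMYND8 and 0.001 in shJARID1D, against list medians of 2.3 and 1.44. These values argue against scaling as the cause of the list's rise relative to other genes. A response to hairpin delivery rather than to loss of the protein could not be told apart, since the labels give 1 hairpin label per target.

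Genes of the G2/M list were lower in shZMYND8. The median closest to 0 was -0.65 without either shZMYND8 library, so a single shZMYND8 library does not account for it. Under the other scalings it was -0.75. Those scalings shifted the median of all genes by at most 0.037 in this comparison, too little for the test to decide on scaling. The list median was -0.78 against -0.005 for all genes, and a factor common to a library's genes cannot set a list apart. These values argue against scaling as the cause of the list's fall relative to other genes. Fewer cycling cells might lower S phase genes and histone genes alike, and the test left this open: the S phase median lay 0.58 above the G2/M median of -0.78, while the histone median lay 0.17 above it.

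Of 20 genes listed at 0 in shLuciferase replicate 2 alone, with at least 50 fragments in each other library, 19 carry the mark of a locus not quantified in that library by the authors' software. The mark accounts for those 19 and went against the prediction that it covers all, since RPS10-NUDT3 carries none. Of the 36 genes marked only there, 23 were matched to a single reference gene, and all 23 lie on the same chromosome of the reference. Had the zeros been kept, 27 of the 36 would have been tested, all 27 with a positive log2 fold change in both knockdowns and medians of 1.03 and 1.1, and edgeR would have called 0. No biological explanation was tested.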
